A study of Homo sapiens and Mus musculus and Rattus norvegicus with 122 samples.

How the data were processed

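The libraries were made from total RNA of cultured human cells or rodent tissue, per the labels' protocols, with a stranded ribosomal RNA depletion kit and paired-end reads of 50 bases on an Illumina sequencer. The authors gave the values of every library as FPKM, fragments scaled to gene length and library size, per the labels and the names of the deposited tables. Aligner, counting tool, genome build, annotation and filters are not given in the sources used here. The tables hold one value per gene identifier and library for 122 libraries, in 6 tables: fibroblasts, tubular epithelial cells, stellate cells, UUO, CCl4 and BDL. All per-sample columns were matched to a sample through the identifiers in the labels. Samples were grouped by cell type or tissue, treatment and time as the labels give them, into 34 groups, and the numbers 1, 2 and 3 after TGFb in the tubular titles were read as replicate numbers. They could also mean isoforms of TGFb, and each treated tubular group would then hold 3 ligands with 1 library each. However, the labels place these libraries in 1 replicate group per time, and the control titles are numbered alike.

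FPKM carries no read number, so depth per library is unknown and small FPKM values have an error that cannot be stated. Values were taken as log2(FPKM + 1), which understates the fold changes of genes near or under 1 FPKM. A gene was tested in a table when its mean reached 1 FPKM in at least 1 group of that table. This kept 13836 of 60448 genes for fibroblasts, 13646 for tubular cells, 13329 for stellate cells, 14094 of 46603 for UUO, 11876 for CCl4 and 13336 of 32545 for BDL. Names were available for 56434 of the 60448 human identifiers, and the tables of mouse and rat genes pair identifiers with no names. Reads of near-identical copies and of overlapping genes may have been divided between genes in a way these tables do not show.

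Each table was fitted with limma 3.58.1 in R 4.3.3 (moderated linear models with a mean-variance trend), with 1 coefficient per group. From these fits came 17 comparisons of treated with control at the same time and 9 differences between such effects (48 h minus 6 h in each culture, cardiac minus lung fibroblasts at each time, UUO day 10 minus day 4, BDL week 5 minus week 3). No 2 comparisons share control libraries. Tests were two-sided, and p-values of genes were adjusted by the method of Benjamini and Hochberg within each comparison. A gene was called at an adjusted p under 0.05. Tables were never pooled, so cultures of different tables were compared only by the overlap of their calls. For calls in the same direction the overlap of independent calls is given beside the observed one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

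Gene lists were written by hand before the data were examined: matrix, TGFb targets, contractile genes, glycolysis, TCA cycle, oxidative phosphorylation, fatty acid oxidation, serine, glycine, proline and one-carbon synthesis, branched-chain amino acid breakdown, cholesterol and fatty acid synthesis, cell division, interferon-stimulated genes, and markers of macrophages, endothelium, epithelium, fibroblasts, injured, proximal and distal tubules and hepatocytes. Each list was tested in the human cultures with camera in limma, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data. The oxidative phosphorylation list holds nuclear-encoded subunits only. Lists with fewer than 5 tested members were only counted. Camera p-values were adjusted by the same method over all lists and comparisons of a table together, and separately over all its differences between effects. Members were also adjusted over the list alone.

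Named genes follow rules set before the data were examined. They are CCN2, ACTA2 and COL1A1 in every human comparison, and the 3 largest rises and falls of each culture at 48 h and of each rodent model at its last time, among called genes of at least 5 FPKM whose groups do not overlap. Added to these are the 2 largest called members of each list with at least 3 called members, the 2 largest differences per direction of each difference between human effects (cardiac minus lung at 48 h), and the 4 genes per direction with the largest smallest change among those called in all 4 cultures. Human genes with clone-style or predicted names, and microRNA, small nucleolar, 5S and U RNA genes, were passed over in the choice by size of change. Genes of the mitochondrial genome and of the Y chromosome, and XIST and TSIX, were passed over too. The limit on names could not be applied to the rodent identifiers, of which 2 per direction are printed, and a choice shared by the 3 rodent models was not made. Some genes these rules or the lists cover are not reported here.

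Before use, the fit was tested on simulated data with 100 genes changed by 1 log2 and 100 by 0.5 log2. All other genes had the same mean in every group, with independent normal errors. A change of 1 log2 was recovered for 99% of genes in the 4 cultures at 48 h, 95% in UUO at day 10, 86% in CCl4, 93% in BDL at week 5, 94% in the cardiac minus lung difference at 48 h and 93% in UUO day 10 minus day 4. For a change of 0.5 log2 these were 81 to 88%, 84%, 50%, 59%, 63% and 34%. Unchanged genes made up 7.32% of the calls in BDL at week 5, 6.55% in cardiac minus lung, 5.22% in UUO day 10 minus day 4 and under 5% elsewhere. In the same treated against control comparisons of the real data 56.4 to 88.7% of genes were called, and the median gene moved. The simulated shares need not hold there. Alternatives were a pseudocount of 0.1, no filter, each library centred on its median gene, the replicate number as a block, a fit of the 2 groups alone, and each library left out in turn. Gene lists were not tested in the rodent tables.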

Results

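The data were RNA-seq libraries from 4 human cell cultures treated with transforming growth factor beta (TGFb), a cytokine that drives matrix production, and from 3 rodent models of organ fibrosis. Cardiac fibroblasts, lung fibroblasts, kidney tubular epithelial cells and hepatic stellate cells, the vitamin A storing cells of the liver that become matrix-producing cells after injury, were sampled with and without TGFb at 6, 24 and 48 h, with 3 libraries in each of 24 groups. The ligand was TGFb1 in the fibroblasts and was given only as TGFb for the other cells. Numbers after it in the tubular titles were read as replicate numbers, as the labels give 1 replicate group, but could mean isoforms. Mouse kidneys were taken 4 or 10 days after unilateral ureteral obstruction (UUO), which blocks the outflow of urine, or a sham operation, with 5 libraries per group. Mouse livers were taken at week 5 of carbon tetrachloride (CCl4), which is toxic to hepatocytes, or from controls, with 5 libraries per group. Rat livers were taken 3 weeks (4 operated, 5 sham) or 5 weeks (5 operated, 6 sham) after bile duct ligation (BDL), which blocks the outflow of bile. The values were FPKM, so the number of reads behind each library is unknown and no counting error can be given. FPKM sums per library ranged from 575015 to 772863 in the human cultures and from 718967 to 916745 in the rodent tissues. Between 11316 and 12835 genes per human library and between 10270 and 14137 per rodent library reached 1 FPKM. Because the origin of the 3 human libraries per group is not stated, p-values there measure only the spread between these samples.

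Each treated group was compared with the control group of its own cell type or tissue and time, to ask which genes, and which groups of metabolic and matrix genes, moved with TGFb or with fibrosis. Large shares of the tested genes moved, and the median gene moved too. Its fitted log2 change lay between -0.33 (stellate cells, 24 h) and 0.025 (cardiac fibroblasts, 6 h) in the human cultures and between 0.27 (CCl4) and 0.76 (BDL, week 5) in the rodent tissues. Counts are therefore given as fitted and relative to the median gene of each library. Genes were named by rules set before the data were examined, and where such a gene passed the test its treated and control values did not overlap unless stated. List members given without a value were named after their values were seen, as were SYNPO2 and PFKM in cardiac fibroblasts.

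**Figure D1:**
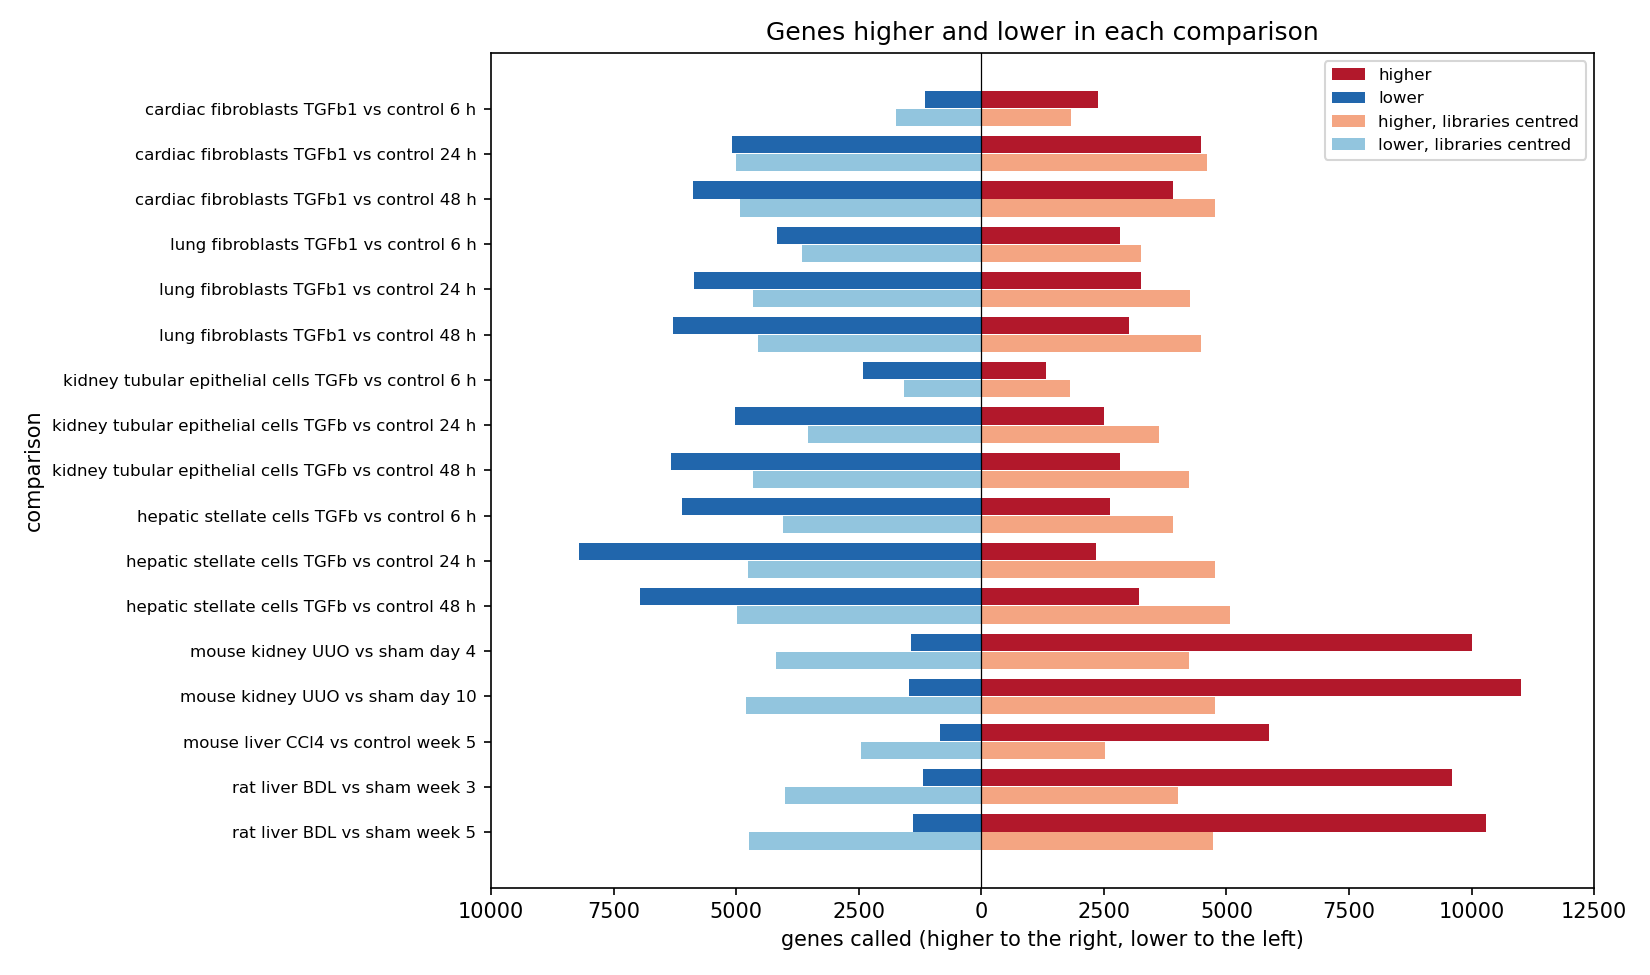
Bars give the number of genes higher (to the right) and lower (to the left) past an adjusted p of 0.05 in each of 17 comparisons, as fitted (dark) and with each library centred on its median gene (pale). In UUO at day 10, 11011 genes were higher and 1484 lower as fitted, against 4765 and 4790 after centring.

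ACTA2 (ENSG00000107796), smooth muscle alpha actin, went from 58.6 ± 1.24 to 2471 ± 168 FPKM in cardiac fibroblasts and from 35.3 ± 0.773 to 1584 ± 83.7 FPKM in lung fibroblasts at 48 h (mean ± SD, n = 3 each), log2 changes of 5.37 (SE 0.13) and 5.45 (SE 0.13) (limma adjusted p = 1.77e-25 and 2.43e-25). Its 48 h log2 change was 2.34 (SE 0.045) in stellate cells and 0.65 (SE 0.085) in tubular cells, where it stayed below 10 FPKM. COL1A1 (ENSG00000108821), the alpha 1 chain of type I collagen, rose at 48 h by 5.70 (SE 0.10) in tubular cells, from 4.54 ± 0.496 to 286 ± 7.24 FPKM, and by 2.499 (SE 0.17) in cardiac fibroblasts, 2.14 (SE 0.17) in lung fibroblasts and 0.67 (SE 0.061) in stellate cells. CCN2 (ENSG00000118523), connective tissue growth factor, rose at each time in both fibroblasts and in stellate cells. At 48 h it went from 32.9 ± 1.21 to 489 ± 19.7 FPKM in cardiac fibroblasts, from 45.8 ± 2.96 to 336 ± 70.2 FPKM in lung fibroblasts and from 48.7 ± 3.36 to 147 ± 2.2 FPKM in stellate cells (limma adjusted p = 1.9e-20, 7.25e-17 and 6.84e-15).

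In tubular cells CCN2 was not shown to differ from control at 48 h as fitted. It rose there at 6 h (0.88, SE 0.050, limma adjusted p = 1.42e-10) and 24 h (0.25, SE 0.050, limma adjusted p = 0.000329) and was 37.5 against 37.3 FPKM at 48 h (0.0063, SE 0.050, limma adjusted p = 0.918), although relative to the median gene it was 0.14 higher (limma adjusted p = 0.017). The 48 h effect was smaller than the 6 h effect for CCN2 in tubular cells (-0.87, SE 0.070) and in stellate cells (-1.65, SE 0.069). In cardiac fibroblasts it was larger for these 3 genes: 2.65 (SE 0.20) for CCN2, 4.84 (SE 0.18) for ACTA2 and 2.39 (SE 0.24) for COL1A1. In lung fibroblasts the effect on ACTA2 (5.14, SE 0.18) and COL1A1 (1.67, SE 0.24) was larger at 48 h than at 6 h, while CCN2 (-0.37, SE 0.20, limma adjusted p = 0.14) was not shown to differ between these times. CCN2 differed (-0.54 and -0.52, limma adjusted p = 0.0235 and 0.0328) when lung control 6 h replicate 1 or TGFb1 48 h replicate 1 was left out. ACTA2 did not pass the test at 6 h (-0.15, SE 0.085, limma adjusted p = 0.225) or 24 h (0.11, SE 0.085, limma adjusted p = 0.305) in tubular cells, nor did COL1A1 at 6 h in cardiac fibroblasts (0.11, SE 0.17, limma adjusted p = 0.701). The 6 h calls in lung fibroblasts of ACTA2 (0.31, SE 0.13, limma adjusted p = 0.0397) and COL1A1 (0.47, SE 0.17, limma adjusted p = 0.0235) each rested on single libraries. Without lung control replicate 2 or 3, or TGFb1 replicate 2 or 3, the adjusted p of ACTA2 was 0.0574, 0.146, 0.113 and 0.172, and without control replicate 2 or 3 or TGFb1 replicate 1 that of COL1A1 was 0.0625, 0.0515 and 0.0636. The 24 h call of COL1A1 in stellate cells (0.17, SE 0.061, limma adjusted p = 0.0194) likewise ended without TGFb replicate 1 (adjusted p = 0.0741) or control replicate 2 (0.109).

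**Figure D2:**
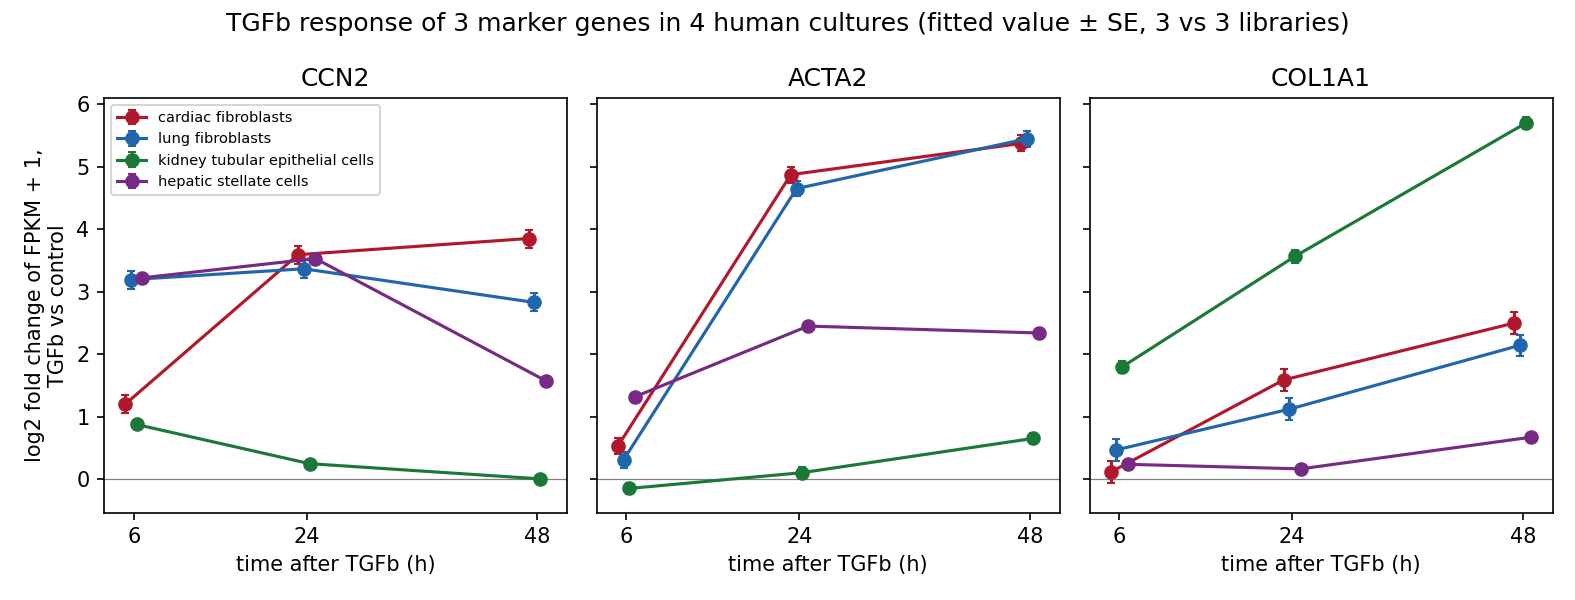
Points give the fitted log2 fold change of FPKM + 1, TGFb against control, with its SE (3 against 3 libraries), of CCN2, ACTA2 and COL1A1 at 6, 24 and 48 h in 4 cultures, joined by lines per culture. ACTA2 reached 5.37 in cardiac and 5.45 in lung fibroblasts at 48 h, and COL1A1 5.70 in tubular cells.

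In cardiac fibroblasts at 48 h most tested contractile, matrix, glycolysis and amino acid synthesis genes rose, and of these lists all but the contractile one passed with an estimated correlation too. CNN1 (ENSG00000130176), the smooth muscle protein calponin 1, went from 0.775 ± 0.125 to 178 ± 6.79 FPKM (mean ± SD, n = 3 each; log2 change 6.66, SE 0.13, limma adjusted p = 2.6e-27). COL10A1 (ENSG00000123500), a network-forming collagen, rose by 6.38 (SE 0.22) and the long noncoding RNA LINC01614 (ENSG00000230838) by 5.47 (SE 0.12). ADH1B (ENSG00000196616), an alcohol dehydrogenase, went from 486 ± 19.8 to 2 ± 0.0934 FPKM (log2 change -7.34, SE 0.17, limma adjusted p = 1.82e-25), and FABP4 (ENSG00000170323), a fatty acid carrier, and VEGFD (ENSG00000165197), a lymphatic growth factor, changed by -6.33 (SE 0.15) and -5.06 (SE 0.10). Of 20 matrix genes 18 rose, among them ELN (elastin, 5.12, SE 0.12) and SPARC (3.16, SE 0.075), and 0 fell. For matrix genes the median was 2.12 (camera adjusted p = 3.51e-13, adjusted p = 0.0199 with an estimated correlation). Contractile genes counted 14 raised and 1 lowered of 16, the latter SYNPO2 at -0.81 (SE 0.10). Contractile genes had a median of 2.34 (camera adjusted p = 6.45e-10, adjusted p = 0.0949 with an estimated correlation). TGFb target and feedback genes rose in 17 of 20, with TGFBI at 3.87 (SE 0.068), and SMAD3, BAMBI and LRRC32 fell. The TGFb target median was 2.12 (camera adjusted p = 6.35e-08, adjusted p = 0.018 with an estimated correlation).

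Glycolysis and lactate export genes rose in 17 of 18 in cardiac fibroblasts at 48 h. For glycolysis genes the median was 1.68 (camera adjusted p = 6.43e-11, adjusted p = 0.035 with an estimated correlation). SLC16A3, a lactate exporter, rose by 3.11 (SE 0.11) and SLC2A1, the glucose transporter GLUT1, by 2.92 (SE 0.067), while the muscle phosphofructokinase PFKM fell (-1.51, SE 0.070). Serine, glycine, proline and one-carbon synthesis genes rose in 18 of 20, with the amino acid transporter SLC7A5 at 4.30 (SE 0.076) and asparagine synthetase, ASNS, at 3.81 (SE 0.081), and GLUL and SHMT1 lower. Amino acid synthesis genes had a median of 1.51 (camera adjusted p = 6.46e-11, adjusted p = 0.00643 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose in 16 of 24 and fell in 3 (LSS, FDFT1 and MVK), led by the desaturase SCD (2.59, SE 0.089) and ACLY (2.03, SE 0.069), which supplies cytosolic acetyl-CoA. The sterol and fatty acid synthesis median was 0.36 (camera adjusted p = 4e-04, adjusted p = 0.338 with an estimated correlation). Fatty acid oxidation genes fell in 16 of 22, such as ACADVL (-1.41, SE 0.064) and the mitochondrial coactivator PPARGC1A (-1.42, SE 0.13), and 2 rose, among them ECI1. For fatty acid oxidation genes the median was -0.88 (camera adjusted p = 0.00149, adjusted p = 0.228 with an estimated correlation). Branched-chain amino acid breakdown genes fell in 14 of 18, with HIBADH at -1.72 (SE 0.056) and MCCC1 at -1.64 (SE 0.066), and HSD17B10 and PCCB rose. Branched-chain amino acid genes had a median of -0.48 (camera adjusted p = 0.0148, adjusted p = 0.179 with an estimated correlation). Tricarboxylic acid (TCA) cycle genes went both ways, 6 higher, with IDH2 at 1.84 (SE 0.061), and 10 lower, with citrate synthase, CS, at -0.88 (SE 0.043), of 21. The TCA cycle median was -0.10 (camera adjusted p = 0.85, adjusted p = 0.947 with an estimated correlation). Oxidative phosphorylation subunits also went both ways, 5 higher and 8 lower of 23, with COX7C at -0.68 (SE 0.084) and COX6C at -0.58 (SE 0.083). For oxidative phosphorylation genes the median was -0.084 (camera adjusted p = 0.905, adjusted p = 0.974 with an estimated correlation). Relative to the median gene these splits were 8 and 8 for the TCA cycle and 9 and 7 for oxidative phosphorylation, and the medians turned to 0.0036 and 0.015.

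Interferon-stimulated genes fell in 13 of 17 in cardiac fibroblasts at 48 h, with IFIT3 at -2.56 (SE 0.15) and IFI44 at -2.20 (SE 0.13), and 2 rose, among them IRF7. Interferon genes had a median of -1.06 (camera adjusted p = 0.0102, adjusted p = 0.5 with an estimated correlation). Cell division genes mostly did not pass the test: 6 of 20 fell, CDK1 at -1.23 (SE 0.23) and CCNB1 at -0.94 (SE 0.22), and BUB1 rose. The cell division median was -0.20 (camera adjusted p = 0.624, adjusted p = 0.932 with an estimated correlation). Fibroblast markers gave 3 raised and 9 lowered of 12, with THY1 at -1.33 (SE 0.10) and COL14A1 at -1.20 (SE 0.090). For fibroblast marker genes the median was -0.61 (camera adjusted p = 0.207, adjusted p = 0.405 with an estimated correlation). Markers of other cell types were few. Of 5 epithelial genes tested, KRT18 (3.91, SE 0.12), KRT7 (2.72, SE 0.13) and KRT8 rose and KRT19 fell (camera adjusted p = 0.198), and of 5 endothelial genes ERG (2.51, SE 0.062), EGFL7 and CLEC14A rose and PECAM1 (-0.78, SE 0.055) and TEK fell (camera adjusted p = 0.683). Of 2 macrophage genes CD68 fell and MSR1 did not pass. All list counts in cardiac fibroblasts at 48 h were the same adjusted over the list alone.

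In numbers, cardiac fibroblasts at 48 h had 3920 genes higher and 5878 lower of 13836 tested (4774 higher and 4927 lower relative to the median gene), with 904 and 1228 changed at least 2-fold (1034 and 1035 after centring). At 24 h 4471 were higher and 5084 lower, and at 6 h 2387 and 1145 (1829 higher and 1748 lower relative to the median gene). At 6 h 17 of 20 TGFb target genes had risen, and so had 14 of 20 serine, glycine, proline and one-carbon genes, but 3 of 20 matrix genes (3 higher and 2 lower after centring; camera adjusted p = 0.428). TGFb target genes had a median at 6 h of 1.09 (camera adjusted p = 5.28e-16, adjusted p = 0.00178 with an estimated correlation). The amino acid synthesis median at 6 h was 0.35 (camera adjusted p = 1.94e-07, adjusted p = 0.0199 with an estimated correlation). At 24 h matrix genes had risen in 17 of 20, and cholesterol and fatty acid synthesis genes in 20 of 24. For matrix genes the median at 24 h was 1.22 (camera adjusted p = 5.77e-08, adjusted p = 0.0949 with an estimated correlation). Sterol and fatty acid synthesis genes had a median at 24 h of 0.61 (camera adjusted p = 1.27e-05, adjusted p = 0.214 with an estimated correlation). Oxidative phosphorylation genes were higher in 15 of 23 at that time and 5 of 23 at 48 h. The oxidative phosphorylation median at 24 h was 0.27 (camera adjusted p = 0.0471, adjusted p = 0.745 with an estimated correlation). Without control replicate 2 or 3 or TGFb1 replicate 3 of 24 h it did not pass (adjusted p = 0.0644, 0.0523 and 0.0631). Cardiac control 24 h replicate 3 had an FPKM sum of 667016 against 739896 and 723082, and with any 1 library left out 9063 to 9193 genes were called at 24 h. The effect at 48 h minus that at 6 h differed for 8029 genes, 2748 upward and 5281 downward (3739 and 3804 relative to the median gene), most steeply upward for CNN1 (6.16, SE 0.18) and COL10A1 (5.90, SE 0.31) and downward for FABP4 (-5.87, SE 0.21) and ADH1B (-5.47, SE 0.24) among genes of at least 5 FPKM.

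In lung fibroblasts at 48 h most contractile, matrix and glycolysis genes rose, and of these lists all but glycolysis passed with an estimated correlation too. IGFBP3 (ENSG00000146674), an insulin-like growth factor carrier, went from 8.24 ± 0.238 to 2268 ± 27.6 FPKM (mean ± SD, n = 3 each; log2 change 7.94, SE 0.13, limma adjusted p = 4.67e-29), ELN (ENSG00000049540) from 4.74 ± 0.695 to 934 ± 19.1 FPKM (log2 change 7.35, SE 0.12) and COMP (ENSG00000105664), a cartilage matrix protein, rose by 5.49 (SE 0.082). ADH1B went from 460 ± 5.85 to 1.18 ± 0.79 FPKM (-7.78, SE 0.17, limma adjusted p = 8.3e-26), and CLEC3B (ENSG00000163815), the plasminogen-binding protein tetranectin, and CLDN11 (ENSG00000013297), a claudin, changed by -4.94 (SE 0.13) and -4.52 (SE 0.064). All 16 contractile genes rose, with ACTG2 at 5.32 (SE 0.19). For contractile genes the median was 1.78 (camera adjusted p = 7.5e-15, adjusted p = 0.0255 with an estimated correlation). Matrix genes rose in 18 of 20, among them COL4A1, a basement membrane collagen (4.41, SE 0.048), and POSTN and TNC did not pass. Matrix genes had a median of 2.11 (camera adjusted p = 7.13e-17, adjusted p = 0.0103 with an estimated correlation). TGFb target genes rose in 15 of 20, with the oxidase NOX4 at 4.58 (SE 0.10) and TGFBI at 3.67 (SE 0.068), and SMAD3 and ID1 fell. The TGFb target median was 1.11 (camera adjusted p = 7.34e-08, adjusted p = 0.018 with an estimated correlation).

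Serine, glycine, proline and one-carbon synthesis genes rose in 18 of 20 in lung fibroblasts at 48 h, ASNS by 2.97 (SE 0.081) and PSAT1, of serine synthesis, by 2.81 (SE 0.082), and GLUL fell. For amino acid synthesis genes the median was 1.12 (camera adjusted p = 1.06e-11, adjusted p = 0.00643 with an estimated correlation). Glycolysis genes rose in 11 of 18 and fell in 4, with PFKP at 1.54 (SE 0.080) and PFKFB3 at -1.15 (SE 0.082), both phosphofructokinase genes, and 11 and 2 did so after centring. Glycolysis genes had a median of 0.30 (camera adjusted p = 0.00358, adjusted p = 0.426 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose in 10 of 24, with SCD at 1.63 (SE 0.089), and 2 fell, among them LSS (-1.55, SE 0.070). Relative to the median gene HMGCS1, MVK, FDFT1, CYP51A1, SC5D, SREBF1 and SREBF2 were called higher in addition, so the rise was broader after centring. The sterol and fatty acid synthesis median was 0.14 (camera adjusted p = 0.00149, adjusted p = 0.405 with an estimated correlation). Fatty acid oxidation genes fell in 15 of 22, PPARGC1A at -1.79 (SE 0.13) and ACADS at -1.06 (SE 0.093), and 3 rose, among them ACSL1 and ECI1. For fatty acid oxidation genes the median was -0.53 (camera adjusted p = 0.0302, adjusted p = 0.426 with an estimated correlation). Branched-chain amino acid breakdown genes fell in 10 of 18, HIBADH at -1.13 (SE 0.056) and AUH at -1.02 (SE 0.095), without a call for the list. Branched-chain amino acid genes had a median of -0.38 (camera adjusted p = 0.109, adjusted p = 0.426 with an estimated correlation). TCA cycle genes split into 7 higher, with SDHB at 1.06 (SE 0.070), and 8 lower, with SUCLG2 at -1.02 (SE 0.062), of 21. The TCA cycle median was -0.070 (camera adjusted p = 0.456, adjusted p = 0.835 with an estimated correlation). Oxidative phosphorylation subunits split into 6 higher, with UQCRC1 at 0.47 (SE 0.059), and 9 lower, with COX6C at -0.48 (SE 0.083), of 23. For oxidative phosphorylation genes the median was -0.070 (camera adjusted p = 0.556, adjusted p = 0.918 with an estimated correlation). Relative to the median gene the TCA cycle split was 9 and 5, that of oxidative phosphorylation 10 and 3 and that of fatty acid oxidation 6 and 14. The medians of the TCA cycle and oxidative phosphorylation turned to 0.075 and 0.075, and for both lists the camera direction was upward while the fitted median and mean were negative.

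Interferon-stimulated genes fell in 15 of 17 in lung fibroblasts at 48 h, IFIT3 at -2.33 (SE 0.15) and IFIT1 at -2.20 (SE 0.20). Interferon genes had a median of -0.74 (camera adjusted p = 0.000858, adjusted p = 0.421 with an estimated correlation). Cell division genes fell in 15 of 20, with AURKA at -0.85 (SE 0.19) and BIRC5 at -0.84 (SE 0.21), and CCNA2 rose, without a call for the list. Relative to the median gene AURKB, RRM2, TYMS, MCM2 and MCM3 lost their call. Levels were low: apart from PCNA the highest control mean was 6.53 FPKM, for MCM3. The cell division median was -0.48 (camera adjusted p = 0.307, adjusted p = 0.844 with an estimated correlation). With the replicate number as a block its adjusted p was 0.0495. Fibroblast markers gave 4 raised and 7 lowered of 12, with TCF21 at -2.56 (SE 0.093) and COL14A1 at -2.53 (SE 0.090). For fibroblast marker genes the median was -0.78 (camera adjusted p = 0.284, adjusted p = 0.426 with an estimated correlation). Of 5 epithelial genes KRT7 (4.47, SE 0.13) and KRT18 (1.82, SE 0.12) rose and KRT19 fell (camera adjusted p = 0.243, list median -0.089 and mean 0.96). Of 5 endothelial genes ERG rose and TEK fell, with 4 higher and 1 lower after centring (camera adjusted p = 0.622, median 0.13 and mean -0.016). Both lay near the floor, ERG going from 0.018 to 0.25 FPKM and TEK from 1.1 to 0.347 FPKM. The 2 macrophage genes CD68 and MSR1 fell. Adjusted over the list alone, the counts of the 48 h lists were the same except for fatty acid oxidation (4 higher and 15 lower) and serine, glycine, proline and one-carbon synthesis (18 and 2).

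The 48 h comparison in lung fibroblasts had 3008 genes higher and 6280 lower of 13836 tested (4473 higher and 4549 lower relative to the median gene), with 546 and 968 changed at least 2-fold (698 and 740 after centring). There were 3265 higher and 5865 lower genes at 24 h (4249 higher and 4657 lower relative to the median gene) and 2834 and 4160 at 6 h. Targets of TGFb had risen in 17 of 20 at 6 h and matrix genes in 14 of 20. TGFb target genes had a median at 6 h of 1.6 (camera adjusted p = 7.46e-15, adjusted p = 0.00178 with an estimated correlation). The matrix median at 6 h was 0.47 (camera adjusted p = 8.64e-08, adjusted p = 0.0949 with an estimated correlation). Serine, glycine, proline and one-carbon genes were 7 higher and 7 lower at 6 h (camera adjusted p = 0.581) and 17 higher and 2 lower at 24 h. For amino acid synthesis genes the median at 24 h was 0.91 (camera adjusted p = 1.01e-08, adjusted p = 0.016 with an estimated correlation). Between 6 and 48 h the effect differed for 6795 genes, 2307 upward and 4488 downward (3181 and 3345 relative to the median gene), upward for IGFBP3 (6.51, SE 0.18) and ACTG2 (5.44, SE 0.26) and downward for ADH1B (-5.05, SE 0.24) and ESM1 (-4.51, SE 0.24). At 24 h 1 TGFb1 and 1 control library stood apart from the others of their groups, with 11916 genes of at least 1 FPKM against 11629 and 11646, and an FPKM sum of 598490 against 699316 and 727413. Without both, a choice made after the values were seen, the contrast lung fibroblasts TGFb1 vs control 24 h gave 9148 called genes against 9130.

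The fibroblasts of heart and lung were compared directly in the same fit, to ask whether the TGFb1 effect itself differed between them. At 48 h the glycolysis genes responded more in cardiac fibroblasts for 17 of 18, with PFKM the exception. Glycolysis genes had a median difference of 1.35 (camera adjusted p = 2.65e-11, adjusted p = 0.0467 with an estimated correlation). CCN2 also responded more in cardiac cells at 48 h (1.02, SE 0.20, limma adjusted p = 0.000105), while ACTA2 (-0.074, SE 0.18, limma adjusted p = 0.76) and COL1A1 (0.36, SE 0.24, limma adjusted p = 0.236) were not shown to differ. GREM1 (ENSG00000166923), a secreted antagonist of bone morphogenetic proteins, changed by 3.46 in cardiac and -1.94 in lung fibroblasts (SE 0.090 each), a difference of 5.40 (SE 0.13). PENK (ENSG00000181195), proenkephalin, differed by 4.99 (SE 0.28), FABP4 by -6.07 (SE 0.21) and CHST2 (ENSG00000175040), a sulfotransferase, by -5.43 (SE 0.16), cardiac minus lung. At 6 h CCN2 (-2.00, SE 0.20, limma adjusted p = 5.49e-09) responded less in cardiac fibroblasts, as did 11 of 20 matrix genes (12 adjusted over the list alone) and 13 of 20 TGFb target genes. The matrix median difference at 6 h was -0.48 (camera adjusted p = 7.3e-11, adjusted p = 0.0467 with an estimated correlation). For TGFb target genes the median difference at 6 h was -0.61 (camera adjusted p = 1.38e-08, adjusted p = 0.0177 with an estimated correlation). CCN2 (0.22, SE 0.20, limma adjusted p = 0.381), ACTA2 (0.22, SE 0.18, limma adjusted p = 0.314) and COL1A1 (0.47, SE 0.24, limma adjusted p = 0.117) did not pass at 24 h, although ACTA2 did without lung TGFb1 replicate 2 (0.40, adjusted p = 0.0467) and COL1A1 without lung control replicate 1 or 2 (0.67 and 0.66, adjusted p = 0.0203 and 0.0227). The effects differed for 3826 genes at 6 h (2590 and 1236; 1749 and 1752 relative to the median gene), 6540 at 24 h (4353 and 2187; 3314 and 2982) and 6600 at 48 h (3801 and 2799; 3426 and 3272) in this fit. In each pair of counts the genes with the higher value in cardiac cells come before those with the lower.

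**Figure D3:**
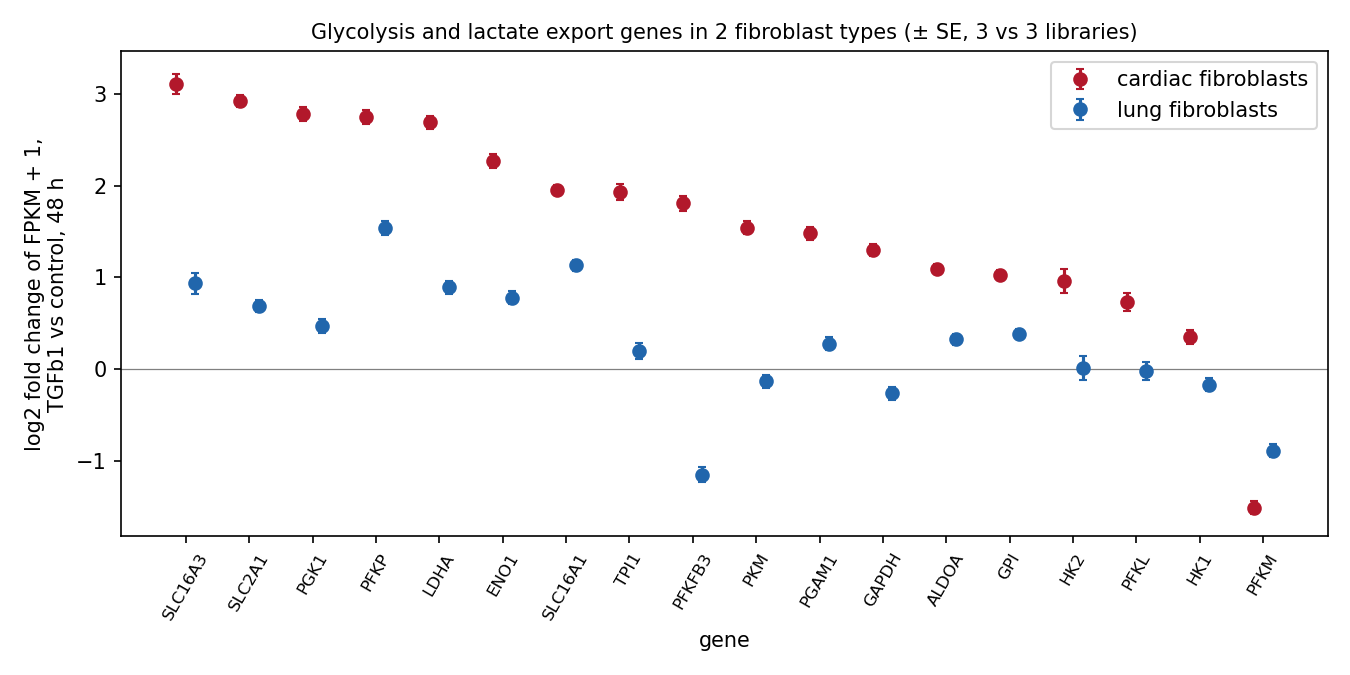
Points give the fitted log2 fold change of FPKM + 1 at 48 h, TGFb1 against control, with its SE (3 against 3 libraries), for 18 glycolysis and lactate export genes in cardiac and lung fibroblasts. The cardiac point lies above the lung point for 17 genes and below it for PFKM.

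In kidney tubular epithelial cells at 48 h most matrix genes rose and most epithelial, TCA cycle and oxidative phosphorylation genes fell, although of these lists only matrix passed with an estimated correlation too. TGFBI (ENSG00000120708), a secreted matrix protein named after its induction by TGFb, went from 94.2 ± 4.85 to 5227 ± 71.9 FPKM (mean ± SD, n = 3 each; log2 change 5.78, SE 0.035, limma adjusted p = 3.8e-25), and TSPAN2 (ENSG00000134198), a tetraspanin, from 0.366 ± 0.188 to 67.5 ± 3.27 FPKM (5.66, SE 0.10). SLC3A1 (ENSG00000138079), a subunit of the cystine transporter of the proximal tubule, went from 48.6 ± 1.8 to 1.44 ± 0.373 FPKM (-4.36, SE 0.11, limma adjusted p = 2.05e-16), and SLC17A3 (ENSG00000124564), an organic anion transporter, and LINC02532 (ENSG00000235142), a long noncoding RNA, changed by -4.19 (SE 0.069) and -4.77 (SE 0.10). All 21 pyruvate dehydrogenase and TCA cycle genes fell, among them DLAT (-1.41, SE 0.048) and IDH3A (-1.32, SE 0.091). TCA cycle genes had a median of -0.77 (camera adjusted p = 1.7e-07, adjusted p = 0.0862 with an estimated correlation). All 23 listed oxidative phosphorylation subunits, nuclear-encoded ones only, fell too, among them ATP5F1B (-1.04, SE 0.035) and COX7B (-0.96, SE 0.048). Relative to the median gene, 21 TCA cycle and 22 oxidative phosphorylation members stayed lower. The oxidative phosphorylation median was -0.74 (camera adjusted p = 4.53e-08, adjusted p = 0.101 with an estimated correlation). Fatty acid oxidation genes fell in 18 of 23, with PPARGC1A at -2.24 (SE 0.087) and ACSL1 at -2.23 (SE 0.039), and ACADVL and ETFB rose. For fatty acid oxidation genes the median was -0.50 (camera adjusted p = 0.00101, adjusted p = 0.114 with an estimated correlation). Branched-chain amino acid breakdown genes fell in 17 of 18, with ACAT1 at -1.503 (SE 0.038) and PCCA at -1.49 (SE 0.041). Branched-chain amino acid genes had a median of -0.77 (camera adjusted p = 2.9e-05, adjusted p = 0.0388 with an estimated correlation).

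Matrix genes rose in 18 of 19 in tubular cells at 48 h, with COL5A1 at 4.12 (SE 0.061), and THBS1 fell. The matrix median was 1.58 (camera adjusted p = 8.74e-16, adjusted p = 0.00654 with an estimated correlation). TGFb target genes rose in 17 of 20, with PMEPA1, an inhibitor of TGFb signaling, at 3.68 (SE 0.070), and SMAD3 and BAMBI fell. For TGFb target genes the median was 1.52 (camera adjusted p = 3.98e-14, adjusted p = 0.00043 with an estimated correlation). Of 11 contractile genes 9 rose, TAGLN by 2.60 (SE 0.067) and TPM1 by 1.47 (SE 0.029), and MYLK and LPP fell. Contractile genes had a median of 0.66 (camera adjusted p = 3.84e-05, adjusted p = 0.0536 with an estimated correlation). Epithelial junction and keratin genes fell in 9 of 11, with the tight junction gene CLDN1 at -3.20 (SE 0.047) and EPCAM at -2.06 (SE 0.081), and KRT7 and CLDN4 rose. The epithelial median was -1.21 (camera adjusted p = 0.00607, adjusted p = 0.129 with an estimated correlation). All 8 proximal tubule genes that could be tested fell, with the fatty acid transporter SLC27A2 at -1.75 (SE 0.083). For proximal tubule genes the median was -1.57 (camera adjusted p = 0.00022, adjusted p = 0.0103 with an estimated correlation). Of 7 fibroblast markers PDGFRB (2.28, SE 0.14), FAP (2.10, SE 0.10), DCN, LUM and THY1 rose and RELN and LRAT fell. Fibroblast marker genes had a median of 0.58 (camera adjusted p = 0.0139, adjusted p = 0.0862 with an estimated correlation). Tubule injury markers went both ways: 5 of 11 rose, with the protease inhibitor TIMP1 at 1.80 (SE 0.050), and 4 fell, with HAVCR1, kidney injury molecule 1, from 199 ± 8.58 to 32.3 ± 1.08 FPKM (-2.59, SE 0.037; camera adjusted p = 0.32). Their median was 0.093 and their mean -0.14. Of 3 distal nephron genes AQP3 rose, KL fell (-0.88, SE 0.071) and KCNJ1 was listed at 0 FPKM in the TGFb group against 2.14 FPKM in the controls. Of 3 macrophage genes CD14 fell (-1.53, SE 0.10) and FCER1G and CD68 rose, and of 3 endothelial genes EGFL7 rose and TIE1 fell (2 and 1 after centring). FCER1G was 1.21 against 0.399 FPKM with overlapping values.

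Cholesterol and fatty acid synthesis genes fell in 22 of 24 in tubular cells at 48 h, HMGCS1 of the mevalonate pathway at -1.33 (SE 0.050) and ELOVL6 at -1.47 (SE 0.059), and ACLY rose. The sterol and fatty acid synthesis median was -0.58 (camera adjusted p = 1.19e-05, adjusted p = 0.0862 with an estimated correlation). Cell division genes fell in 19 of 20, with CDC20 at -1.29 (SE 0.055) and AURKA at -1.26 (SE 0.050). For cell division genes the median was -0.72 (camera adjusted p = 1.19e-05, adjusted p = 0.0577 with an estimated correlation). Interferon-stimulated genes fell in 12 of 15, with IFI35 at -1.06 (SE 0.086) and IFIT1 at -0.95 (SE 0.15), and IRF7 rose. Interferon genes had a median of -0.60 (camera adjusted p = 0.035, adjusted p = 0.206 with an estimated correlation). Without control replicate 3 the interferon list had a camera adjusted p of 0.0539. Glycolysis genes rose in 9 of 18 and fell in 6, with PFKP at 1.00 (SE 0.033) and SLC2A1 at 0.86 (SE 0.047). The glycolysis median was 0.10 (camera adjusted p = 0.0923, adjusted p = 0.651 with an estimated correlation). After centring 12 rose and 5 fell, and the list's adjusted p was 0.049. Serine, glycine, proline and one-carbon genes split into 6 higher and 10 lower of 20, with SHMT1 at -2.49 (SE 0.059) and PSAT1 at -1.98 (SE 0.041) (camera adjusted p = 0.964), 9 and 8 relative to the median gene, and their median turned from -0.11 to 0.025. All list counts in tubular cells at 48 h were the same adjusted over the list alone.

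**Figure D4:**
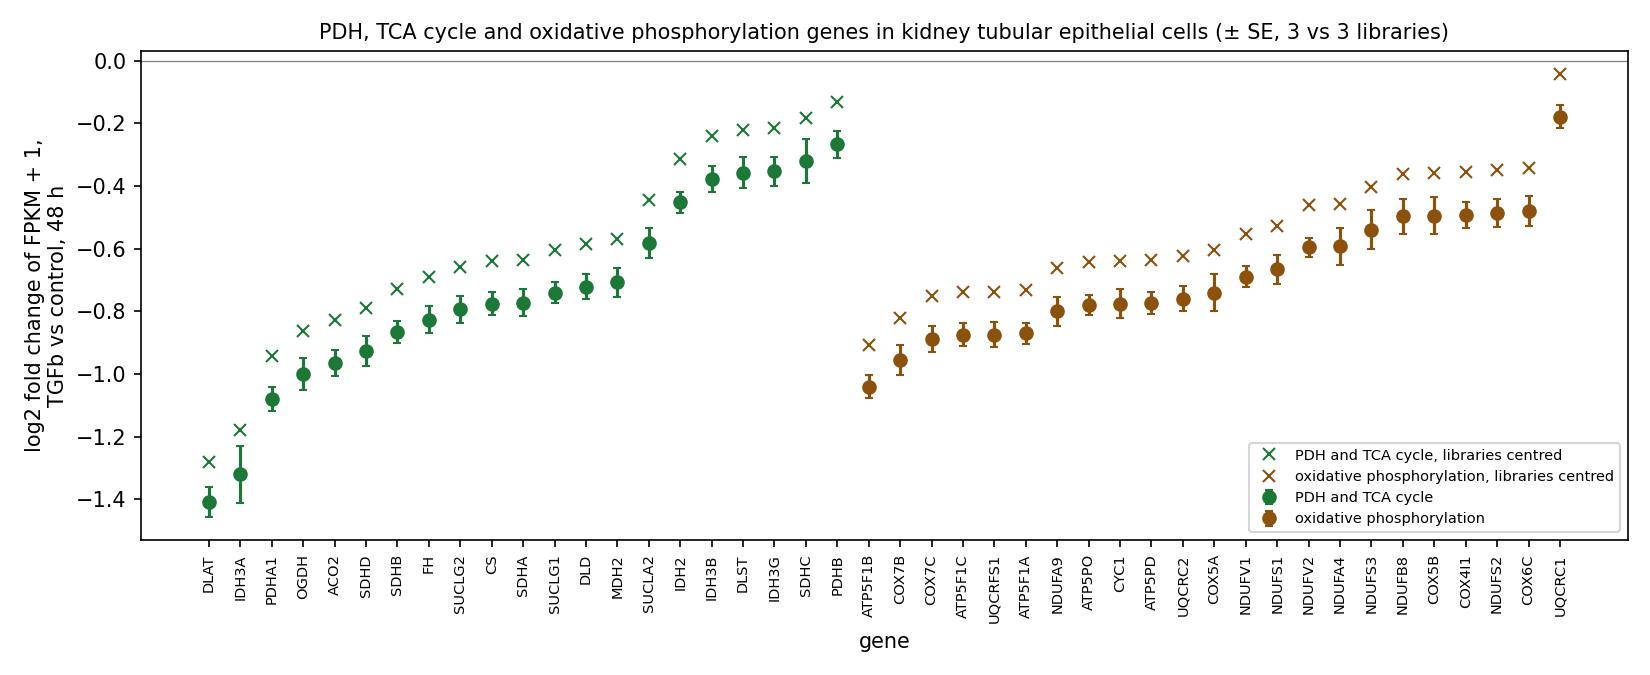
Circles give the fitted log2 fold change of FPKM + 1 at 48 h, TGFb against control, with its SE (3 against 3 libraries), of 21 pyruvate dehydrogenase (PDH) and TCA cycle genes and 23 oxidative phosphorylation genes in tubular cells, and crosses the value with each library centred on its median gene. All 44 circles lie below 0, from -1.41 for DLAT upward, and the oxidative phosphorylation genes are nuclear-encoded ones.

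At the earlier times fewer of these genes were called in tubular cells. TCA cycle genes were lower in 5 of 21 at 6 h and 19 of 21 at 24 h, and oxidative phosphorylation genes in 6 of 23 and 22 of 23. For TCA cycle genes the median at 6 h was -0.087 (camera adjusted p = 0.0854, adjusted p = 0.579 with an estimated correlation). TCA cycle genes had a median at 24 h of -0.32 (camera adjusted p = 3.14e-05, adjusted p = 0.136 with an estimated correlation). The oxidative phosphorylation median at 6 h was -0.078 (camera adjusted p = 0.149, adjusted p = 0.681 with an estimated correlation). For oxidative phosphorylation genes the median at 24 h was -0.30 (camera adjusted p = 2.64e-05, adjusted p = 0.165 with an estimated correlation). The TCA cycle list passed at 6 h without control replicate 2 (adjusted p = 0.0281) or TGFb replicate 1 (0.0494). At 6 h TGFb target genes had risen in 16 of 20, and matrix genes in 16 of 19 at 24 h. TGFb target genes had a median at 6 h of 0.82 (camera adjusted p = 4.27e-19, adjusted p = 0.000229 with an estimated correlation). The matrix median at 24 h was 0.92 (camera adjusted p = 2.79e-14, adjusted p = 0.00707 with an estimated correlation). Tubular cells had 2830 genes higher and 6333 lower of 13646 tested at 48 h (4244 higher and 4651 lower relative to the median gene), with 538 and 790 changed at least 2-fold (672 and 604 after centring). At 24 h the counts were 2513 and 5022 (3625 higher and 3542 lower relative to the median gene), and at 6 h 1320 and 2420 (1811 higher and 1585 lower relative to the median gene). The 48 h effect differed from the 6 h effect for 6680 genes, 2173 upward and 4507 downward (2969 and 3505 relative to the median gene), upward for the integrin subunit ITGA11 (4.68, SE 0.10) and TGFBI (4.62, SE 0.049) and downward for FXYD2 (-3.95, SE 0.059), a regulator of the sodium pump, and SLC3A1 (-3.69, SE 0.16).

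In hepatic stellate cells at 48 h most cell division genes and fibroblast and stellate cell markers fell, and most matrix and contractile genes rose. None of these lists passed with an estimated correlation. INHBE (ENSG00000139269), an activin subunit, went from 0.183 ± 0.0812 to 31 ± 2.86 FPKM (mean ± SD, n = 3 each; log2 change 4.76, SE 0.10, limma adjusted p = 2.42e-17) and COMP rose by 4.67 (SE 0.056). RN7SL471P (ENSG00000263426), annotated as a pseudogene copy of the signal recognition particle RNA, went from 63.9 ± 11.5 to 4471 ± 194 FPKM (6.12, SE 0.079, limma adjusted p = 7.42e-20). ITLN1 (ENSG00000179914), a secreted lectin, went from 292 ± 14 to 1.1 ± 0.167 FPKM (-7.12, SE 0.066, limma adjusted p = 3.52e-21), and SHISA3 (ENSG00000178343) and ADH1B changed by -6.04 (SE 0.081) and -5.97 (SE 0.078). Cell division genes fell in 19 of 20, with TOP2A at -2.70 (SE 0.075) and CDK1 at -2.44 (SE 0.10), and PCNA did not pass. For cell division genes the median was -1.71 (camera adjusted p = 1.73e-05, adjusted p = 0.195 with an estimated correlation). Fibroblast and stellate cell markers fell in 10 of 11, among them DCN, decorin (-2.83, SE 0.048), and COL14A1 (-3.06, SE 0.059), and FAP rose. Fibroblast marker genes had a median of -1.04 (camera adjusted p = 0.0311, adjusted p = 0.319 with an estimated correlation). Relative to the median gene these markers were 2 higher and 6 lower. Matrix genes rose in 17 of 20, with ELN at 3.63 (SE 0.056) and COL4A1 at 2.61 (SE 0.035), and TNC fell. The matrix median was 0.90 (camera adjusted p = 8.95e-11, adjusted p = 0.078 with an estimated correlation). Contractile genes rose in 12 of 16, with ACTG2 at 2.27 (SE 0.075), and SYNPO2, LMOD1 and TGFB1I1 fell (13 higher and 1 lower after centring). For contractile genes the median was 0.81 (camera adjusted p = 2.06e-06, adjusted p = 0.226 with an estimated correlation). TGFb target genes rose in 13 of 20, with NOX4 at 3.37 (SE 0.074), and fell in 5, with the signal transducer SMAD3 at -3.17 (SE 0.072). TGFb target genes had a median of 0.87 (camera adjusted p = 3.04e-05, adjusted p = 0.12 with an estimated correlation).

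Serine, glycine, proline and one-carbon genes rose in 16 of 20 in stellate cells at 48 h, with SLC7A5 at 2.86 (SE 0.060) and ASNS at 2.51 (SE 0.062), and GLUL and GOT2 fell. The amino acid synthesis median was 0.80 (camera adjusted p = 2.68e-08, adjusted p = 0.078 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose in 14 of 24 and fell in 6, with SCD at 1.46 (SE 0.069) and FDPS at 1.38 (SE 0.040). For sterol and fatty acid synthesis genes the median was 0.39 (camera adjusted p = 0.00013, adjusted p = 0.289 with an estimated correlation). Glycolysis genes rose in 10 of 18 and fell in 6, with SLC16A3 at 1.55 (SE 0.042) and PFKP at 1.36 (SE 0.047). Glycolysis genes had a median of 0.11 (camera adjusted p = 0.00896, adjusted p = 0.416 with an estimated correlation). After centring the glycolysis split was 14 and 1, and that of cholesterol and fatty acid synthesis 17 and 4. TCA cycle genes were 7 higher and 8 lower of 21, with SUCLG1 at -1.31 (SE 0.043) (camera adjusted p = 0.371), with a median of 0.041 and a mean of -0.072. Oxidative phosphorylation genes were 5 higher and 11 lower of 23, with NDUFS1 at 0.63 (SE 0.041) and UQCRC2 at -0.66 (SE 0.054) (camera adjusted p = 0.7). Fatty acid oxidation genes were 5 higher and 9 lower of 21, with ETFDH at 0.89 (SE 0.071) and ECI2 at -0.91 (SE 0.063) (camera adjusted p = 0.893), and branched-chain amino acid breakdown genes 5 higher and 11 lower of 18, with HIBADH at -1.19 (SE 0.054) and BCAT2 at -0.98 (SE 0.061) (camera adjusted p = 0.7). Relative to the median gene these splits became 13 and 6, 13 and 4, 9 and 8, and 6 and 7. The medians of oxidative phosphorylation and fatty acid oxidation, for which camera gave an upward direction, turned from -0.058 to 0.17 and from -0.13 to 0.10. Interferon-stimulated genes fell in 11 of 15, IFIT1 at -2.48 (SE 0.072) and IFIT3 at -1.19 (SE 0.11), and ISG15 rose, without a call for the list (3 higher and 8 lower after centring; camera adjusted p = 0.182). Of 4 hepatocyte genes tested ASS1, of the urea cycle, rose (2.16, SE 0.046) and CPS1 (-1.67, SE 0.074), APOA1 and CYP27A1 fell. Macrophage markers MSR1 (-0.90, SE 0.12), CD14 (-0.66, SE 0.10) and CD68 fell. Endothelial TEK (-2.80, SE 0.057), KDR and FLT1 fell and CLEC14A (0.78, SE 0.082) and EGFL7 rose (camera adjusted p = 0.924). Epithelial KRT7 (3.12, SE 0.12) and KRT8 rose while KRT19 (-2.60, SE 0.12), CLDN1 and KRT18 fell (camera adjusted p = 0.925). Adjusted over the list alone the 48 h counts were the same except for oxidative phosphorylation, with 4 higher and 11 lower.

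Stellate cells had 3222 genes higher and 6963 lower of 13329 tested at 48 h (5078 higher and 4982 lower relative to the median gene), with 531 and 1707 changed at least 2-fold (880 and 1136 after centring). Control 48 h replicate 1 had an FPKM sum of 595847 against 705544 and 669406 and 39.9% of it in the 10 most abundant genes against 47.52% and 48.64%, and with any 1 library left out 9800 to 10134 genes were called at 48 h. At 24 h there were 2330 higher and 8212 lower (4773 higher and 4762 lower relative to the median gene), and at 6 h 2625 and 6098 (3914 higher and 4036 lower relative to the median gene). All 20 cell division genes were lower at 24 h, all 16 contractile genes were higher, and TGFb target genes had risen in 17 of 20 at 6 h. The cell division median at 24 h was -1.84 (camera adjusted p = 1.65e-06, adjusted p = 0.14 with an estimated correlation). For contractile genes the median at 24 h was 1.61 (camera adjusted p = 9.06e-18, adjusted p = 0.0647 with an estimated correlation). TGFb target genes had a median at 6 h of 1.12 (camera adjusted p = 3.14e-14, adjusted p = 0.0295 with an estimated correlation). Cholesterol and fatty acid synthesis genes had risen in 17 of 24 at 6 h. The sterol and fatty acid synthesis median at 6 h was 0.39 (camera adjusted p = 4.34e-08, adjusted p = 0.13 with an estimated correlation). The effect changed between 6 and 48 h for 8306 genes, 3219 upward and 5087 downward (4101 and 4311 relative to the median gene), upward for RN7SL471P (5.58, SE 0.11) and INHBE (4.90, SE 0.14) and downward for ITLN1 (-6.60, SE 0.094) and the cathepsin CTSV (-4.62, SE 0.085).

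To ask what the 4 cultures shared at 48 h, calls were matched by gene identifier over 11981 genes tested in all. TSPAN2 rose in each, by 5.11 in cardiac and 4.91 in lung fibroblasts, 5.66 in tubular cells and 3.67 in stellate cells (SE 0.087, 0.087, 0.10 and 0.068). TGFBI (3.87, 3.67, 5.78 and 2.45), the matrix proteoglycan BGN (2.75, 2.74, 2.73 and 2.32) and IGFBP3 (4.08, 7.94, 2.31 and 3.04) rose in the same order of cultures. ITGB8, an integrin subunit that binds latent TGFb, fell in each (-2.55, -2.54, -2.89 and -2.79), as did PLAAT4 (-3.41, -3.00, -2.13 and -3.04), the protease ADAMTS1 (-2.25, -2.22, -2.48 and -2.03) and the selenium carrier SELENOP (-3.65, -4.38, -1.82 and -5.39). In all 4 cultures 541 genes were raised, against 41.3 if the calls were independent, and 1424 lowered, against 526. Relative to the median gene these counts were 986 (181 if independent) and 678 (159 if independent). At least 2-fold, 56 genes were raised (0.0374 if independent) and 52 lowered (0.254 if independent) in all 4. The sizes of effects in different cell types outside the fibroblast fit were not tested against each other.

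**Figure D5:**
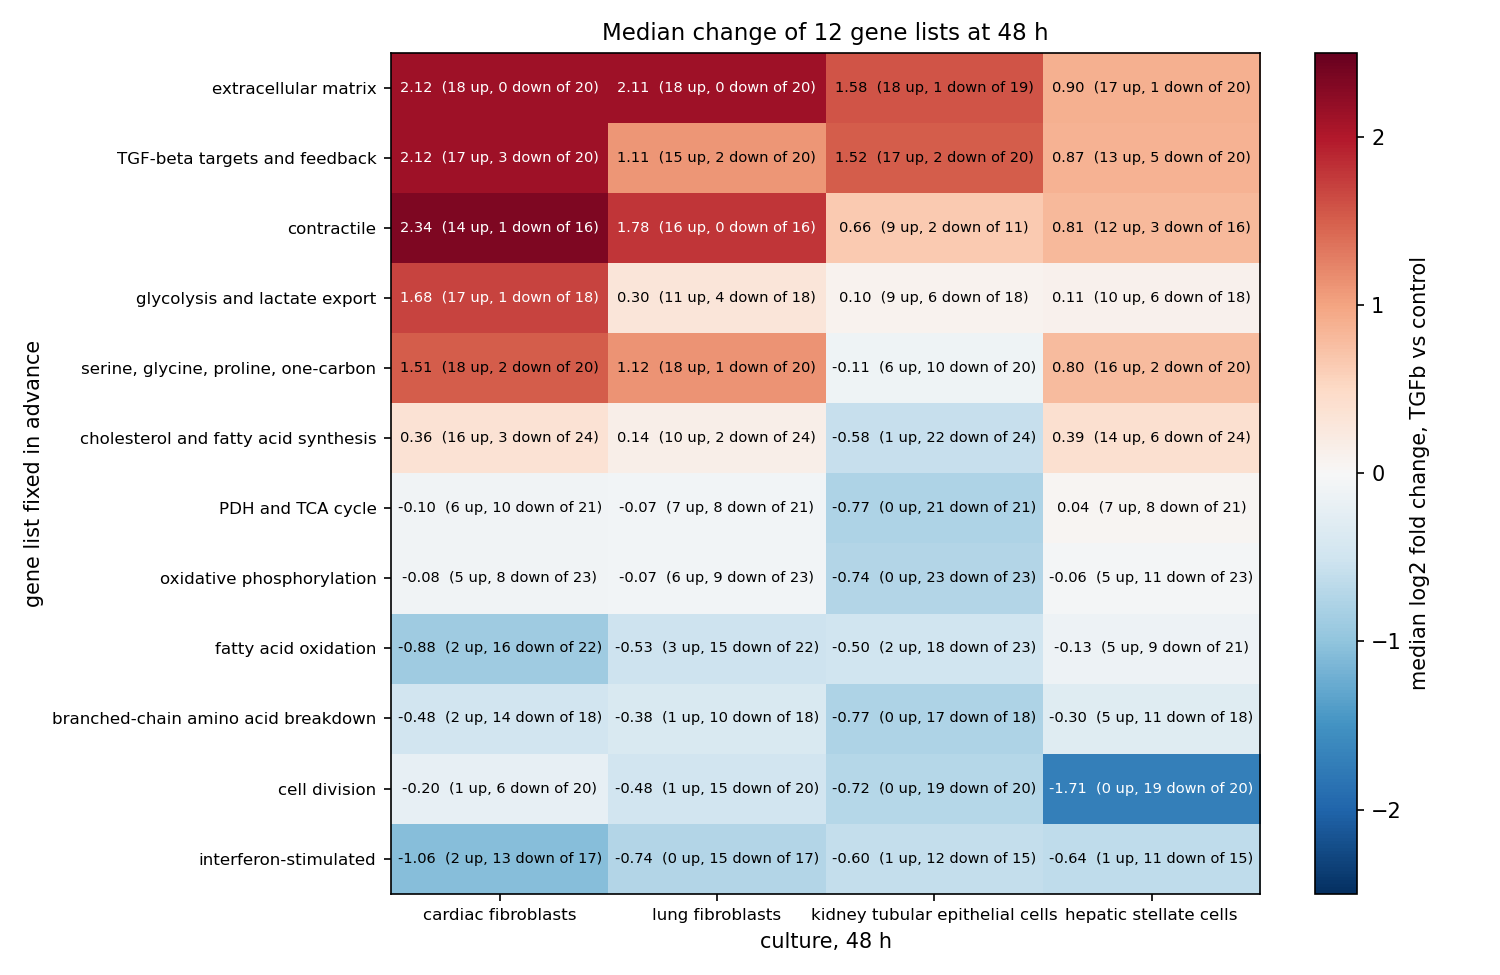
Each cell gives the median log2 fold change of FPKM + 1 at 48 h, TGFb against control, of 1 of 12 gene lists in 1 of 4 cultures, with the members called higher and lower (3 against 3 libraries). Matrix medians run from 0.90 to 2.12, and the TCA cycle list stands at -0.77 in tubular cells, 21 of 21 members lower, against -0.10 in cardiac fibroblasts, where the sign turns after centring.

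In the obstructed mouse kidney, compared with sham kidneys to ask what obstruction changed, most genes that moved were higher. The rodent tables pair their identifiers with no gene names, so genes are given by identifier and the gene lists were not tested there. At day 10 ENSMUSG00000040405 went from 0.79 ± 0.194 to 326 ± 97.2 FPKM (mean ± SD, n = 5 each; log2 change 7.48, SE 0.20, limma adjusted p = 5.9e-17) and ENSMUSG00000026822 from 0.86 ± 0.308 to 238 ± 112 FPKM (6.91, SE 0.27, limma adjusted p = 4.98e-15). ENSMUSG00000096852 went from 31.1 ± 7 to 3.03 ± 2.43 FPKM (-3.23, SE 0.37, limma adjusted p = 5.75e-08) and ENSMUSG00000028017 from 192 ± 8.58 to 27.9 ± 15.6 FPKM (-3.06, SE 0.37, limma adjusted p = 1.51e-07). At day 10 there were 11011 genes higher and 1484 lower of 14094 tested (4765 higher and 4790 lower relative to the median gene), 3466 and 364 of them at least 2-fold as fitted against 1041 and 1166 after centring, and at day 4 10014 and 1443 (4232 higher and 4179 lower relative to the median gene). The effect at day 10 differed from that at day 4 for 3208 genes, 2903 upward and 305 downward, but for 1500 relative to the median gene (725 and 775).

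In mouse liver after 5 weeks of CCl4, ENSMUSG00000026822, which also rose in UUO, went from 3.19 ± 1.59 to 127 ± 30.2 FPKM (mean ± SD, n = 5 each; log2 change 4.99, SE 0.24, limma adjusted p = 1.82e-07) and ENSMUSG00000001506 from 0.68 ± 0.343 to 44.1 ± 20.8 FPKM (4.62, SE 0.31, limma adjusted p = 1.39e-06). ENSMUSG00000096674 and ENSMUSG00000078673 fell, from 1237 ± 1350 to 2.13 ± 1.68 FPKM and from 2556 ± 1830 to 23.8 ± 27.1 FPKM, with log2 changes of -7.26 (SE 1.27) and -6.91 (SE 0.87) and control levels that spread widely. There were 5862 genes higher and 838 lower of 11876 tested (2514 higher and 2461 lower relative to the median gene), 919 and 126 of them at least 2-fold as fitted against 521 and 253 after centring. To ask what the 2 mouse models shared, calls of UUO day 10 and CCl4 were matched over 11294 genes tested in both, an overlap chosen after the data were seen. Both models raised 5094 genes (4526 if independent) and lowered 257 (67.8 if independent), and 536 genes were called in opposite directions. Relative to the median gene 1547 were raised (848 if independent), 1302 lowered (767 if independent) and 682 opposite. For the opposite calls no count under independence was computed, so they do not show whether the models diverge.

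In rat liver after bile duct ligation, compared with sham livers, ENSRNOG00000013973 and ENSRNOG00000002843 rose at week 5, from 1.29 ± 0.859 to 389 ± 179 FPKM and from 0.0598 ± 0.0814 to 118 ± 47.1 FPKM (mean ± SD, n = 5 operated and 6 sham), log2 changes of 7.37 (SE 0.33) and 6.72 (SE 0.21). ENSRNOG00000043131 and ENSRNOG00000047613 fell, from 1485 ± 258 to 0.865 ± 1.45 FPKM and from 4367 ± 399 to 5.05 ± 3.57 FPKM, log2 changes of -9.88, SE 0.31, limma adjusted p = 1.4e-15, and -9.73, SE 0.57, limma adjusted p = 4.43e-12. At week 5 there were 10302 genes higher and 1401 lower of 13336 tested (4726 higher and 4732 lower relative to the median gene), 4673 and 549 of them at least 2-fold as fitted against 1431 and 1444 after centring, and at week 3 9594 and 1198 (4012 higher and 4005 lower relative to the median gene). The effects of weeks 5 and 3 differed for 1952 genes, 1733 upward and 219 downward, and relative to the median gene for 1093 (574 and 519). That count rested on single libraries and on the method, with 733 and 748 genes without BDL week 3 replicate 2 or 5, 3465 without replicate 4, 1039 with a pseudocount of 0.1 and 344 with the replicate number as a block.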

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

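Tests of a few abundant genes, a fixed share of reads and the scaling of libraries were written only after the results were seen. So were all counts of other splits. Those of one scaling factor, other short noncoding RNA, expression level and transcript length were written before their own outcome was seen. These too followed patterns already seen in the data.

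More genes were raised than lowered in the 3 rodent models. The median gene shifted by 0.649 log2 in UUO at day 10, 0.279 in CCl4 and 0.761 in BDL at week 5. If a few abundant genes taking most of the FPKM were the whole cause, the FPKM sum without the 10 most abundant genes would shift as much, but the median shift exceeded it by 0.368 (SE 0.0231), 0.306 (SE 0.048) and 0.661 (SE 0.0347). One scaling factor for every gene would move genes of all levels alike. Among genes of at least 5 FPKM, the 25% with the highest level shifted less than the 25% with the lowest. The differences were -0.363 (SE 0.0257), -0.183 (SE 0.0587) and -0.569 (SE 0.0278). The highest 25% also rose, by 0.36, 0.0945 and 0.24, so this counts only against one factor as the whole cause. No biological explanation was tested, and a change in cell composition or in the total RNA per cell stays open.

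RN7SL471P rose in stellate cells at 48 h from 63.9 to 4470 FPKM (n = 3 each), while the related RN7SL1 went from 64500 to 118000, RN7SL2 from 62800 to 122000 and RN7SL3 from 305 to 3630 FPKM. A fixed share of the reads of RN7SL1 and RN7SL2 would leave the ratio to them unchanged, and it rose by 5.17 log2 (SE 0.132). More short noncoding RNA in the TGFb libraries would raise the others too, and the median of 64 other short noncoding genes changed by -0.00455 log2 (SE 0.278), with 32 higher and 0 raised by 1 log2 or more. A different assignment of reads between near-identical copies stays open, and no biological explanation was tested. These tests covered stellate cells alone. At 48 h RN7SL471P also went from 9.86 to 59.9 FPKM in cardiac fibroblasts and from 3.91 to 12.9 FPKM in lung fibroblasts. In tubular cells it went from 14 to 9.07 FPKM.

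All 44 listed TCA cycle and nuclear-encoded oxidative phosphorylation genes fell in tubular cells at 48 h. With each library centred on its median gene, 43 stayed lower, which speaks against the scaling of the libraries as the whole cause. Of 10000 random lists matched on expression level, and of as many matched on transcript length, a share of 1e-04 had a median as low, the smallest that this number of lists can give. The members' median was -0.75 against a lowest random median of -0.41 in both cases. Random lists treat genes as independent, and with an estimated correlation the camera adjusted p was 0.0862 and 0.101. A lower mitochondrial programme under TGFb is therefore a hypothesis that may be tested elsewhere. Most listed proximal tubule, epithelial, cell division and sterol synthesis genes fell in this comparison too, and most matrix genes rose.

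Several effects differed between times or between the fibroblasts, by the test of the difference itself (log2 values). For cardiac minus lung fibroblasts these were CCN2 -1.995 at 6 h and CCN2 1.024, GREM1 5.395, PENK 4.994, FABP4 -6.073 and CHST2 -5.432 at 48 h. The effect at 48 h minus that at 6 h was CCN2 2.653, ACTA2 4.844, COL1A1 2.385, CNN1 6.164, COL10A1 5.903, FABP4 -5.871 and ADH1B -5.466 in cardiac fibroblasts. In lung fibroblasts it was ACTA2 5.136, COL1A1 1.672, IGFBP3 6.513, ACTG2 5.442, ADH1B -5.046 and ESM1 -4.507. Tubular cells gave CCN2 -0.8697, ACTA2 0.7998, COL1A1 3.9, ITGA11 4.675, TGFBI 4.618, FXYD2 -3.95 and SLC3A1 -3.694. Stellate cells gave CCN2 -1.648, ACTA2 1.019, COL1A1 0.4349, RN7SL471P 5.584, INHBE 4.899, ITLN1 -6.601 and CTSV -4.62.

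Cardiac and lung fibroblasts also differed in list medians. At 6 h the cardiac minus lung median was -0.481 for matrix genes, -0.613 for TGFb target genes, 0.22 (camera adjusted p = 0.0217, adjusted p = 0.398 with an estimated correlation) for serine, glycine, proline and one-carbon genes and 0.367 (camera adjusted p = 0.0331, adjusted p = 0.68 with an estimated correlation) for interferon-stimulated genes, which did not pass without cardiac TGFb1 6 h replicate 2 (adjusted p = 0.156) or lung TGFb1 6 h replicate 1 (0.0918). By 24 h it was -0.518 (camera adjusted p = 0.000136, adjusted p = 0.346 with an estimated correlation) for matrix, 0.765 (camera adjusted p = 0.0233, adjusted p = 0.662 with an estimated correlation) for contractile and 0.673 (camera adjusted p = 4.97e-06, adjusted p = 0.255 with an estimated correlation) for cholesterol and fatty acid synthesis genes. The contractile difference did not pass without lung TGFb1 24 h replicate 1 (adjusted p = 0.0628). At 48 h it was 0.716 (camera adjusted p = 0.0179, adjusted p = 0.384 with an estimated correlation) for TGFb target genes and 1.35 for glycolysis. Fatty acid oxidation genes differed by -0.329 (camera adjusted p = 0.0157, adjusted p = 0.419 with an estimated correlation) at 48 h, and serine, glycine, proline and one-carbon genes by 0.439 (camera adjusted p = 0.00105, adjusted p = 0.219 with an estimated correlation).

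Among 54 groups of values from 4 to 6 libraries, of which chance marks about 1 in 20, 5 held a library far from the others. UUO day 4 replicate 4 had an FPKM sum of 734977 (nearest 757157) and 13191 genes of at least 1 FPKM (nearest 13343). Rat sham week 5 replicate 1 held 51.1% of its FPKM in the 10 most abundant genes (nearest 53.1%) and 0.218 FPKM of ENSRNOG00000002843 (nearest 0.0567). BDL week 5 replicate 1 had 3.43 FPKM of ENSRNOG00000043131 (nearest 0.618).

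Other splits of the libraries into groups of the same sizes were fitted in the same way. For each of the 12 human comparisons the 10 possible splits are too few to give a share under 0.05. The real one, the 1 split as large in each, called 3532 to 10542 genes and the highest other split 0 or 1, except in lung fibroblasts at 24 h, where another split called 1711 against 9130. For the rodent models only the real split of 100 reached its count. This makes chance less likely but cannot exclude it, and outside CCl4 some other splits also called many genes. These counts, real and highest other, were 11457 and 7242 in UUO day 4, 12495 and 9968 in UUO day 10, 6700 and 4 in CCl4, 10792 and 9612 in BDL week 3, and 11703 and 10877 in BDL week 5. For the differences between effects, the other splits moved libraries between times or cell types. Such splits mix these within a group, which adds spread, set them against each other, or both. Their counts therefore cannot decide on chance. Real and highest other counts were 3208 and 1190 in UUO day 10 minus day 4. In BDL week 5 minus week 3 they were 1952 and 1476. Several alternatives there gave counts below 1476, and no other splits were fitted under them. For 48 h minus 6 h, 2 of 100 splits, the real one included, were as large in cardiac fibroblasts (8029, highest other 9173). In lung fibroblasts 2 were (6795 and 7838), in tubular cells 4 (6680 and 7906) and in stellate cells 2 (8306 and 9277). For cardiac minus lung, 7 splits at 6 h (3826 and 11049), 6 at 24 h (6540 and 9963) and 9 at 48 h (6600 and 8132) were as large, the real one included. The others as large moved unequal numbers of treated and control libraries and so set the 2 cell types against each other. Among the 41, 35 and 44 other splits that moved equal numbers, none was as large and the highest called 0, 2 and 0 genes. These mix the 2 cell types within each group, which adds spread, so few calls were likely whatever the effects. They cannot decide on chance either. The 4 overlaps, of 541, 1424, 5094 and 257 genes, were reached by the real split alone of 100, with 0 as the highest other. Other splits called at most 1 gene in each culture at 48 h and at most 4 in CCl4. An overlap near 0 was thus nearly certain beforehand. It does not show whether cultures or models share more genes than independent calls would.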

How the results depend on the processing

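Of the alternatives tried, the omission of both outlying lung libraries at 24 h and the overlap of the 2 mouse models were chosen after seeing the data. No call of a named gene or list test reversed under any alternative. The direction changed, with no call in either fit, for 21 list tests without the filter, 6 under centring, 3 with a pseudocount of 0.1 and 1 with the replicate block, and for 16 list tests and 3 named gene results with some library left out. Single genes did under centring, where calls turned from higher to lower for 1884 genes in UUO day 10, 737 in UUO day 4, 1931 in BDL week 5 and 969 in BDL week 3, and from lower to higher for 372 in stellate cells at 24 h, 40 at 48 h and 2 in tubular cells at 48 h. Of 30 counts of genes, 29 stayed within 1.5 times under a pseudocount of 0.1, 30 without the filter, 24 under median centring, 23 of 24 with the replicate block and 17 of 17 in a fit of the 2 groups alone. Centring moved UUO day 10 minus day 4 from 3208 to 1500 genes, BDL week 5 minus week 3 from 1952 to 1093, the overlap of the 4 cultures from 541 to 986 raised and from 1424 to 678 lowered, and that of the mouse models from 5094 to 1547 raised and from 257 to 1302 lowered, since it takes out the shift of the median gene. The BDL difference gave 1039 genes with a pseudocount of 0.1 and 344 with the replicate block, and from 733 (without BDL week 3 replicate 2) to 3465 (without BDL week 3 replicate 4) with 1 library left out, and the cause was not tested. Same-numbered libraries did not deviate together (correlations of -0.206 to 0.268, with no comparison above 0.1 in every pair), so the numbers were not taken as pairs. The stellate titles number the libraries in a single run across groups and state no pairs, so no block was fitted there. Paired by order within groups, the 3 stellate pairs at 48 h had correlations of 0.0359 to 0.214, each library closest to its own number. The block ended no call of a named gene or list and brought 5 list tests past the threshold. Of 289 list tests, 93 lost their call with an estimated correlation, 1 lost it and 9 gained it under centring, 3 gained it with a pseudocount of 0.1, and 37 gained it without the filter. With some library left out, 15 of these tests lost the call and 9 gained it. Of 258 named gene results, the call of 257 was the same under centring and of 258 with a pseudocount of 0.1, and with some library left out 3 lost it and 3 gained it. Without both outlying lung libraries, the contrast cardiac minus lung fibroblast TGFb1 effect 24 h had 6844 genes against 6540. The planned overlap of mouse and rat genes by name was not run, because the identifiers could not be named, and the lymphocyte and bile duct lists, meant for rodent tissue, were not tested. With depth unknown, a gene at or near 0 FPKM sets no limit on its true level.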

Other observations

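The genes named in this part, and the placing of libraries below, were chosen after the values were seen. SMAD3, which carries the TGFb signal to the nucleus, was lower at 48 h in cardiac fibroblasts, lung fibroblasts, tubular cells and stellate cells, with log2 changes of -1.23, -2.70, -1.13 and -3.17. In the same order PFKM changed by -1.51, -0.89, -0.72 and -0.58 and LSS, lanosterol synthase of the cholesterol pathway, by -0.86, -1.55, -1.05 and -1.14. KRT7, a keratin of simple epithelia, was higher in each (2.72, 4.47, 0.88 and 3.12), and so was FAP, a fibroblast surface protease (0.89, 0.73, 2.10 and 1.10).

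Along the axis from the mean of the control to the mean of the treated libraries of each comparison (0 and 1), over the genes called at least 2-fold and with the library's own values left out of the means, human treated libraries lay between 0.934 and 1.04 and human controls between -0.0179 and 0.0448. Rodent treated libraries lay between 0.694 and 1.24 and rodent controls between -0.109 and 0.0711, so no library lay on the side of the other group. The genes were chosen with the library included, which favours this outcome. No 2 libraries were identical.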
